A study of Mus musculus with 8 samples.

How the data were processed

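RNA was measured in B-cell precursors sorted from the bone marrow of adult C57BL/6 mice that were heterozygous or wild-type for Ebf1. Per the labels, pro-B cells were sorted as B220+ CD19+ CD43high IgM− and pre-B cells as B220+ CD19+ CD43low/neg IgM−. The 4 groups, wild-type and heterozygous pro-B and pre-B cells, held 2 arrays each, which the labels number 1 and 2. Per the labels' protocols, RNA was extracted with RNeasy Micro columns, amplified in a dual amplification, labelled and hybridized to Affymetrix mouse expression arrays. The number of cells behind each array is not given, and neither is how many mice each array stands for. The intensities were computed with RMA by the authors, per the series' design text, and were deposited as 1 value per probe set and array. RMA corrects background, normalizes between arrays and summarizes the probes of a probe set. Its version and settings are not given in the sources used here. The deposited intensities had medians from 15.7 to 17.0 and maxima from 14466 to 16262, so they were read as linear and taken to log2, with no further normalization between arrays.

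The table held 45101 probe sets, of which 64 were AFFX controls. The platform annotation named 1 gene symbol for 34958 probe sets and several for 932, and it listed no gene for 9211. Gene identifiers of 34754 single-gene probe sets were in the RefSeq gene table, which changed 0 symbols. No gene was named from a probe set with several symbols. Each of 18194 genes was represented by its probe set with the highest mean over the 8 arrays, and other probe sets of named genes were compared by sign. Genes were tested if this mean reached the 50th percentile of all probe set means (4.053 on the log2 scale, a linear intensity of 16.6), which kept 11003. Cd19, Vpreb2, Lyn, Ccnb1, Ighd, Sell, Isg15 and Stat1 had no probe set of their own in the annotation and Kit lay below the filter, so these genes were not analysed here. Ebf1 was tested on each of its 5 probe sets.

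Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with the 4 group means was fitted to all 8 arrays, so that groups of 2 arrays shared 1 estimate of the spread per gene (4 residual degrees of freedom, 3.26 prior degrees of freedom). Empirical Bayes moderated t-tests gave p, which was adjusted by the Benjamini-Hochberg method over genes within a comparison, and an adjusted p under 0.05 counted as passing. The 6 comparisons were heterozygous against wild-type in pro-B cells, in pre-B cells and averaged over both, the interaction of genotype and stage, and pre-B against pro-B cells within each genotype. Ebf1 probe sets were adjusted over the 5 probe sets and also over all 45037 probe sets other than controls. For 26 gene lists of pathways, stages and other cell types, shifts were tested with camera at its preset correlation of 0.01 and adjusted over the lists. Members of a list were also adjusted over the list alone. Differences within a replicate number were computed from the 2 arrays with that number and carry no test. Figures were drawn with matplotlib 3.10.9 and NumPy 2.4.6 in Python 3.11.15.

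Groups, comparisons, lists, filters, most alternatives and the rule for named genes were fixed before the data were examined. In the genotype comparisons and the wild-type stage comparison the rule took up to 12 genes in each direction with the largest change among those that passed. If fewer than 5 passed in a direction, those with the smallest p were added up to 5 and given as not passing. In the interaction and the heterozygous stage comparison the number was 5. Clone names, predicted genes and sex-linked genes were counted but not named. From each list described, up to 4 members with the smallest p were taken, and markers such as Spn, Il2ra, Igll1, Vpreb1, Rag1, Pax5, Cd79a and Myc were always eligible. Other members of lists, such as Ighm, Mcm2, Ncl or Klf6, and the control genes Xist, Eif2s3y and S100a8 were chosen as examples after their values were seen.

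Whether the replicate numbers pair the samples was checked from the data, since the labels do not say. The differences between replicate 2 and replicate 1 correlated across genes in each of the 6 pairs of groups, with r from 0.234 to 0.569, and from 0.201 to 0.56 without sex-linked genes. The numbers were therefore used as a block in an alternative fit with 3 residual degrees of freedom. Other alternatives were a stricter filter at the 70th percentile, no filter, every probe set, the mean of a gene's probe sets, no _x_at or _s_at probe sets and renewed quantile normalization. Further ones were arrays centred on their medians, array weights, a mean trend or robust prior in the empirical Bayes step, a fold change of at least 1.5 beside the adjusted p, the 4 arrays of a comparison alone, and each array left out in turn. Lists were also tested with camera at an estimated correlation and with fry. The genotype comparison averaged over both stages was repeated over 34 splits of the 8 arrays into groups of 4, the real one included and the split by stage left out, with stage as a covariate.

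The methods were tested on simulated data with the means and spread of the 11003 genes, 200 changed genes and 10 simulations a comparison. Each gene had the same spread in all groups, so a spread that differs between stages was not covered. Of genes changed by 1 log2 unit, 25.9% were found in the pro-B, 22.5% in the pre-B, 55.3% in the averaged and 24.6% in the wild-type stage comparison. Of genes changed by 2 log2 units, 72%, 71.8%, 89.5% and 75% were found. False calls made up 4.86%, 4.26%, 5.05% and 3.21% of calls, and 100% of true calls had the right direction. Camera found a list shifted by −0.5 in 10 of 10 simulations and called 1 of 240 tests of lists that were not shifted. Genes were drawn independently there. These counts therefore say nothing of false calls among lists whose genes move together, such as mitosis, with an estimated correlation of 0.535. No deposited array was left out of the main results.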

Results

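Gene expression was measured in B-cell precursors of adult mouse bone marrow that carried either 1 or 2 working copies of Ebf1, which encodes a transcription factor of early B-cell development. The cells were sorted as pro-B cells, with high surface CD43, or as pre-B cells, with low or no CD43. Both sorts required B220 and CD19 and excluded IgM. Heterozygous and wild-type mice were on the C57BL/6 background. Each of the 4 groups had 2 arrays, so 8 arrays were compared, and their number limits the precision. The labels number the arrays of a group 1 and 2 without saying how many mice each stands for, so every standard error and p describes only the spread between these arrays. They also do not say whether the pro-B and pre-B cells of a genotype came from the same mice. Where both stages were averaged, the 4 arrays of a genotype were counted as independent and may stand for fewer animals.

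The arrays had alike levels, with median intensities from 15.7 to 17.0 on the deposited linear scale. Correlation between the arrays of a group, across genes, was 0.978 in wild-type and 0.985 in heterozygous pro-B cells, and 0.938 and 0.933 in pre-B cells. The first principal component held 63.2% of the variance and parted the stages. The second held 17.2% and parted replicate 1 from replicate 2 among the pre-B arrays. Xist, transcribed from the inactive X chromosome, stood between 11.2 and 11.7 on the log2 scale on every replicate 1 array and between 1.92 and 2.44 on every replicate 2 array. The Y-linked gene Eif2s3y was at 8.33 to 9.12 on the replicate 2 arrays, so replicate number coincided with the sex of the mice, and the arrays of a group came from different animals. Granulocyte transcripts were abundant on both pre-B replicate 2 arrays: S100a8 was at 12.8 in wild-type and 13.1 in heterozygous cells there, against 4.02 and 6.84 on the replicate 1 arrays. The Gapdh control probe sets of heterozygous pre-B replicate 1 differed by 4.39 log2 units between the 3' and 5' ends, against 2.28 to 2.85 on the other 7 arrays, a measure of RNA shortening. The table holds no background level, so differences against a mean below the filter, 4.053 on the log2 scale, are given without a fold and are not exact, nor are orders by size that rest on them.

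Whether the genotype labels showed in Ebf1 itself was asked first. The array carries 5 probe sets for Ebf1, here lettered A to E in the order of their identifiers, and A to D had lower means in heterozygotes at both stages. On probe set C, wild-type pro-B cells had log2 intensities of 8.95 and 8.76 and heterozygous ones 8.45 and 8.65, while pre-B cells had 9.14 and 8.86 against 8.35 and 7.87. On probe set D the values were 9.29 and 9.21 against 8.61 and 8.75 in pro-B cells, and 9.13 and 9.0 against 8.68 and 8.05 in pre-B cells. On probe set B they were 9.69 and 9.52 against 9.35 and 9.40 in pro-B cells, and 9.51 and 9.39 against 9.05 and 8.53 in pre-B cells. On probe set A they were 10.14 and 9.70 against 9.41 and 9.77, and 10.78 and 10.14 against 9.92 and 9.79. Probe set E went the other way, at 4.92 and 5.55 against 8.64 and 8.36 in pro-B cells, and at 5.86 and 5.80 against 7.59 and 7.72 in pre-B cells.

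**Figure D1:**
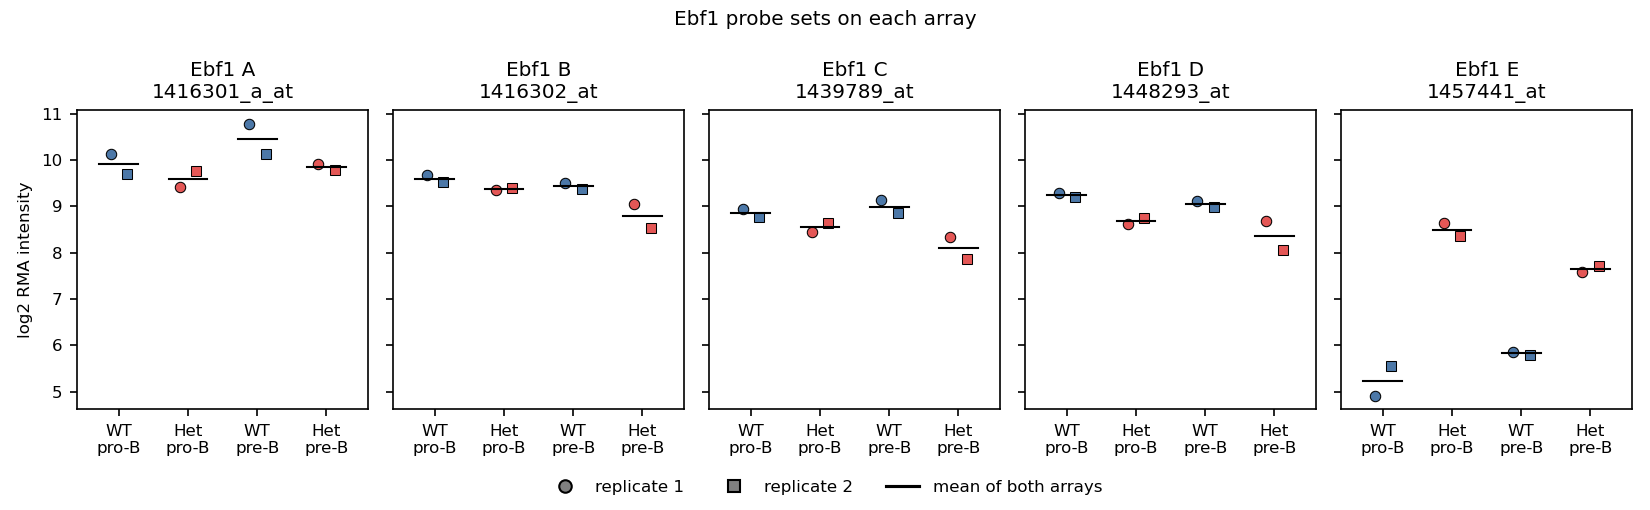
Log2 RMA intensity (vertical axis) of the 5 Ebf1 probe sets on each of the 8 arrays, by group (horizontal axis). Circles are replicate 1, squares are replicate 2 and each line is the mean of both arrays: probe set E rose from 5.24 to 8.50 in pro-B cells, while the means of A to D lay lower in heterozygotes at both stages.

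Averaged over both stages, Ebf1 fell on probe set C by 0.60 ± 0.15 (SE, 4 arrays against 4), to 0.662 of the wild-type level (adjusted p = 0.00941 over the 5 probe sets). It also fell on probe set D (−0.64 ± 0.16, adjusted p = 0.00941), B (−0.45 ± 0.15, adjusted p = 0.0221) and A (−0.47 ± 0.19, adjusted p = 0.0438). In pre-B cells alone C passed (−0.89 ± 0.22, adjusted p = 0.0109), as did B (−0.66 ± 0.21, adjusted p = 0.021) and D (−0.70 ± 0.22, adjusted p = 0.021). In pro-B cells none of A to D passed, with values between −0.57 and −0.23 and adjusted p from 0.0932 to 0.298. Without single arrays the pro-B values ran from −0.55 to −0.11 for A and −0.31 to −0.15 for B. They ran from −0.41 to −0.21 for C and −0.64 to −0.51 for D. The interaction passed for E alone (−1.45 ± 0.33, adjusted p = 0.0162). Over all probe sets none of A to D passed, while E passed averaged over both stages (2.54 ± 0.17, limma adjusted p = 0.0229). Probe set E rose 9.63-fold in pro-B cells (3.27 ± 0.24, adjusted p = 0.0298 over all probe sets) and, over the 5 probe sets, 3.53-fold in pre-B cells (1.82 ± 0.24, adjusted p = 0.000511; 0.0989 over all probe sets). The labels do not say which part of Ebf1 was altered, and a probe set outside that part checks nothing.

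The averaged calls of C and D passed without any single array, at an adjusted p of 0.0417 at most, and so did that of E (7.29e-05 at most). Other Ebf1 calls were lost without single arrays. In pre-B cells the calls of B, C and D were lost without wild-type replicate 1 and without heterozygous replicate 2. Without the latter B had −0.40 and D −0.38. The averaged call of A was lost without wild-type pro-B replicate 1 (0.14), heterozygous pro-B replicate 1 (0.138), wild-type pre-B replicate 1 (−0.31, 0.131), heterozygous pre-B replicate 1 (0.0653) or heterozygous pre-B replicate 2 (0.0992), and when the arrays were quantile normalized again (0.0641). That of B was lost without wild-type pro-B replicate 1 (0.0727), heterozygous pro-B replicate 1 (0.0667) or wild-type pre-B replicate 1 (0.0619). Without either heterozygous pre-B array, D passed in pro-B cells (adjusted p = 0.0215). Without wild-type pre-B replicate 2, A passed in pre-B cells (−0.93, adjusted p = 0.0229), as it did with arrays centred on their medians (adjusted p = 0.041).

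The genes that differed by genotype whichever the stage were asked about next, by averaging the 2 genotype differences. The test took pro-B and pre-B arrays as independent, although both may stem from the same mice. Reln, which encodes the secreted protein reelin, fell (−3.46 ± 0.39, SE, 4 arrays against 4): its wild-type means of 6.94 in pro-B and 10.9 in pre-B cells stood against 3.81, below the filter, and 7.12 in heterozygotes. Mmp14, a membrane-bound matrix protease, fell by 1.68 ± 0.13, from 7.29 to 4.85 in pro-B and from 5.25 to 4.33 in pre-B cells. Ets2, a transcription factor of the ETS family, fell by 1.53 ± 0.16, from 7.17 to 5.62 and from 8.57 to 7.05. Nid1, a basement membrane protein, rose by 1.61 ± 0.17, with pre-B means of 3.57 and 6.20 and pro-B means of 3.26 and 3.84, all but 6.20 below the filter.

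In all 8 of 11003 tested genes passed, 1 higher and 7 lower, and 947 had an unadjusted p under 0.05 where 550 are expected by chance. Besides these 4, Oaf (−2.25 ± 0.23) and the secreted protease gene Adamts7 (−2.22 ± 0.23) fell. The peptidase gene Thop1 fell by 1.34 ± 0.13, and Aph1b, which encodes a subunit of γ-secretase, the protease that releases the Notch intracellular domain, fell by 1.26 ± 0.13. Adjusted p ran from 0.035 for Mmp14 to 0.0478 for Reln. The genes with the smallest p among the others above 0 did not pass: St8sia6 at 2.20 (adjusted p = 0.103), Evi2a at 1.11 (0.124), Pgap1 at 1.5 and Cxcr5 at 1.22 (both 0.134). A second probe set carried the same sign for Aph1b (−1.21), Ets2 (−1.06) and Nid1 (0.79), and a dimmer one lay near 0 for Thop1 (−0.11). The 2 other probe sets of Mmp14 lay at −0.07 and 0.10, so its call rests on 1 of 3.

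**Figure D2:**
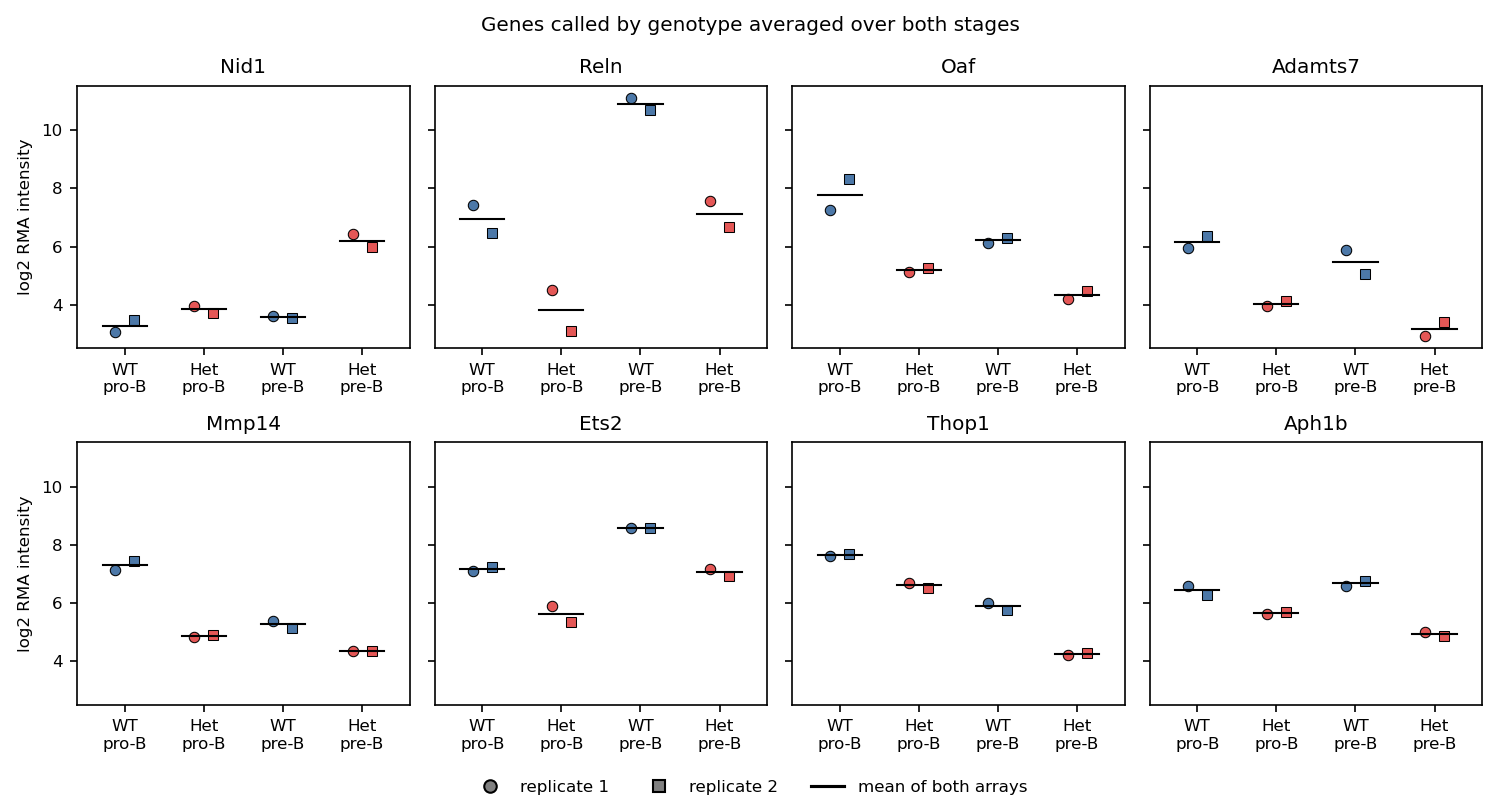
Log2 RMA intensity (vertical axis) of the 8 genes called in the averaged genotype comparison, on each array by group (horizontal axis). Circles are replicate 1, squares are replicate 2 and lines are means of both arrays: Reln stood at 6.94 and 10.9 in wild-type pro-B and pre-B cells and at 3.81 and 7.12 in heterozygotes.

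With replicate number as a block 23 genes passed in the averaged comparison (8 higher and 15 lower), the same 8 among them. Evi2a then passed (adjusted p = 0.0459), and Reln had an adjusted p of 0.00376. The count was small enough for 1 array to decide it: it was 6 without wild-type pre-B replicate 2, 1 without wild-type pro-B replicate 1, and 0 without wild-type pro-B replicate 2, wild-type pre-B replicate 1 or any 1 of the 4 heterozygous arrays. When every probe set was tested 1 passed, none of the 8 genes, and when the probe sets of a gene were averaged 0 did. Array weights ended the calls of Nid1, Oaf and Aph1b (adjusted p = 0.0518 each), Ets2 (0.0725) and Reln (0.0951), and the trend that of Aph1b (0.058). Without both pre-B replicate 2 arrays Reln, Oaf and Ets2 (0.0582 each) and Aph1b (0.0583) did not pass. Reln also lost its call with no filter (0.061) and after renewed quantile normalization (0.0561), and its value was −1.88 when its probe sets were averaged, the other one being dim (−0.30). St8sia6 passed without wild-type pre-B replicate 2 (adjusted p = 0.0383).

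Pro-B cells were compared to ask what 1 copy of Ebf1 changed at the earlier stage. Mmp14 fell by 2.44 ± 0.19 (SE, n = 2 arrays a group), or 5.41-fold (adjusted p = 0.0292), and was the only gene of 11003 to pass in limma. Unadjusted p was under 0.05 for 215 genes, fewer than the 550 expected by chance. The spread per gene was shared with the pre-B arrays, whose replicates correlated less (0.938 and 0.933, against 0.978 and 0.985). A shared spread may be too wide for pro-B cells, so this count does not show an absence of change. Next by p among values below 0, and not passing, were Oaf at −2.60 ± 0.33 (adjusted p = 0.446), Ets2 at −1.55 ± 0.22, Adamts7 at −2.13 ± 0.32 and Thop1 at −1.05 ± 0.18 (all 0.657), each of which passed in the averaged comparison. Above 0 none passed. The smallest p belonged to Adgrl2 (1.14 ± 0.18), a light-chain V gene of the Igkv9 family (1.62 ± 0.26), Evi5 (1.66 ± 0.28, with −0.19 on another probe set), the cytokine receptor gene Csf2rb2 (1.55 ± 0.27) and Il10ra (1.26 ± 0.23), all at an adjusted p of 0.657. The block gave 2 genes, both lower and Mmp14 among them (adjusted p = 0.0347).

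Mmp14 lost its pro-B call without any 1 of the 8 arrays. Its adjusted p was 0.135 without wild-type pro-B replicate 1 and 0.554 without replicate 2, 0.841 and 0.732 without heterozygous pro-B replicates 1 and 2, 0.0782 without either wild-type pre-B array and 0.106 without either heterozygous one. The 4 pro-B arrays alone gave 0.0645, with its value unchanged at −2.44. Its value was −0.82 when its 3 probe sets were averaged (adjusted p = 1), and the trend gave 0.0503.

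Of the gene lists, mature B cell markers lay above 0 in heterozygous pro-B cells. The list holds genes of antigen presentation and of the mature B-cell surface. Their median was 0.40 with 20 of 21 measured members above 0 (camera adjusted p = 6.78e-09; adjusted p = 0.624 with an estimated correlation), and the medians within replicates 1 and 2 were 0.47 and 0.32. Cxcr5, a chemokine receptor, had 1.09 ± 0.28, the invariant chain gene Cd74 had 0.90, Cd40 had 0.68 and H2-Aa had 0.53, while no member passed over all genes or adjusted over the list alone. Cell-cycle genes lay below 0. All 32 measured members of the mitosis and G2/M list did, with a median of −0.26 (camera adjusted p = 2.01e-06; adjusted p = 0.801 with an estimated correlation). They included the spindle motor gene Kif11 at −0.54 ± 0.19 and the cyclin gene Ccna2 at −0.54, and the medians within replicates were −0.20 and −0.31. Without heterozygous pro-B replicate 2 the median was −0.15. Of the 34 genes of DNA replication and G1/S, 33 lay below 0, with a median of −0.19 (camera adjusted p = 2.41e-05; adjusted p = 0.795 with an estimated correlation). The helicase gene Mcm2 had −0.36 and Rfc4 −0.32, and the medians within replicates were −0.07 and −0.31. Without wild-type pro-B replicate 2 the median was −0.12. Adjusted over the list alone, 0 members of either cell-cycle list passed.

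The interferon response list had a median of 0.31 in pro-B cells, with 21 of 23 members above 0 (camera adjusted p = 5.07e-05; adjusted p = 0.801 with an estimated correlation). Its medians within replicates 1 and 2 were 0.41 and 0.20. The antiviral genes Oasl2 (1.23 ± 0.33) and Ifit1 (1.16) and the GTPase gene Gbp3 (0.54) did not pass over all genes, and 0 members passed adjusted over the list alone. The list call was lost without wild-type pro-B replicate 2 (median 0.20, adjusted p = 0.112) or heterozygous pro-B replicate 1 (0.14, 0.206), and the median was 0.52 without heterozygous pro-B replicate 2. The dendritic and plasmacytoid list had a median of 0.23 over 12 members (camera adjusted p = 0.0027; adjusted p = 0.624 with an estimated correlation). Its medians within replicates were 0.23 and 0.23, and the call was lost without wild-type pro-B replicate 2 (adjusted p = 0.164). Adjusted over the list alone, 1 member rose, Cox6a2 (0.96 ± 0.18, adjusted p = 0.0119), and Ly6d had 0.43. MYC targets and ribosome biogenesis, with a median of −0.08 over 30 members, passed camera only just (adjusted p = 0.0476; adjusted p = 0.939 with an estimated correlation). That call was lost with the block (adjusted p = 0.0561), with no filter (0.0713), after renewed quantile normalization (0.0709), without wild-type pro-B replicate 1 (median −0.14, 0.159) or 2 (−0.015, 0.221), and without heterozygous pro-B replicate 2 (0.051, 0.838). The median was −0.22 without heterozygous pro-B replicate 1. Within replicates 1 and 2 the medians were 0.14 and −0.27, of opposite sign.

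The genes that EBF1 and PAX5 activate in the B lineage did not pass as a list in pro-B cells. The median of 26 members was 0.05, with 18 above 0 (adjusted p = 0.148), and 0 passed adjusted over the list alone. The surrogate light chain genes Igll1 (−0.13) and Vpreb1 (0.01), Pax5 (−0.09), Cd79a (0.26) and Rag1 (0.23) stayed within 1 SE of 0 or, for Cd79a, within 2. Meis1, a homeobox gene of stem and progenitor cells, fell when adjusted over the list alone, by 1.26 ± 0.28 (adjusted p = 0.0475 in the pro-B list and 0.0317 in the stem list), and had an adjusted p of 0.968 over all genes.

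Pre-B cells were compared to ask the same question at the later stage. St8sia6, a sialyltransferase gene, had 4.01 ± 0.42 (SE, n = 2 arrays a group), between means of 3.41, below the filter, and 7.42. Nid1 had 2.62 ± 0.23, Pgap1 2.75 ± 0.34, Pcp4 3.12 ± 0.44 and Maoa 1.29 ± 0.21, and of these Nid1, Pcp4 and Maoa also had wild-type means below the filter, as Ect2 had in heterozygotes. Below 0, the cytoskeletal gene Epb41l4b had −2.34 ± 0.24, the cytokinesis gene Ect2 −2.48 ± 0.29, Aph1b −1.74 ± 0.19, Thop1 −1.64 ± 0.18 and Gh −1.51 ± 0.17. None of them passed: adjusted p was 0.0626, and 0.0716 for Pcp4 and 0.0826 for Maoa. The 3 other Gh probe sets gave −1.85, −1.69 and −1.83, while the 2 dim other probe sets of Epb41l4b gave 0.00 and 0.24.

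In limma 0 genes passed in pre-B cells, although 1385 had an unadjusted p under 0.05, 346 above 0 and 1039 below, against 550 expected by chance. The spread shared with pro-B cells may be too narrow here, which would raise this count. Adding the replicate number as a block let 22 genes pass, 4 higher and 18 lower. Among them were St8sia6, Nid1, Epb41l4b, Aph1b, Thop1 and Ect2 (adjusted p = 0.0408 each) and Pgap1, Pcp4 and Gh (0.0451 each), but not Maoa (0.0511). Without wild-type pre-B replicate 2, 13 genes passed, St8sia6 (adjusted p = 0.0275), Ect2 (0.0275) and Pgap1 (0.0482) among them. Across genes the pro-B and pre-B differences correlated with r = 0.265 (0.153 to 0.273 without single arrays) and rho = 0.188, genes not being independent replicates. Of genes with an unadjusted p under 0.05 at both stages, 35 lay above 0 at both, where 3.96 are expected by chance. Below 0 at both lay 40, where 8.40 are expected, and 10 had opposite signs, where 14.7 are. These expected counts take the comparisons as independent, yet both used the same spread per gene. Genes of small spread can reach a small p in both for that reason, so the excess was not tested.

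Cell division genes stood lower in heterozygous pre-B cells. All 32 members of the mitosis and G2/M list lay below 0, with a median of −1.10 (camera adjusted p = 9.98e-19; adjusted p = 0.569 with an estimated correlation), and the medians within replicates were −1.11 and −0.90. Over all genes 0 members passed, while adjusted over the list alone 23 fell and 27 did so with the block. These included Ect2 (−2.48, adjusted p = 0.0015), Kif11 (−1.28 ± 0.19, adjusted p = 0.00419), the ubiquitin-conjugating gene Ube2c (−1.42 ± 0.23, adjusted p = 0.00419) and Birc5 (−1.26 ± 0.22, adjusted p = 0.0049). Genes of DNA replication and G1/S had a median of −0.66 with 31 of 34 below 0 (camera adjusted p = 8.23e-09; adjusted p = 0.569 with an estimated correlation), and −0.72 and −0.57 within replicates. Adjusted over the list alone 10 fell, 14 with the block. Among the 10 were Cdc45 (−1.41 ± 0.19), E2f2 (−1.25 ± 0.20) and Cdc6 (−1.61 ± 0.26), each with an adjusted p of 0.00443, and the clamp loader gene Rfc3 (−1.09 ± 0.22, adjusted p = 0.012). Heterozygous pre-B replicate 1, the array with the largest Gapdh difference, did not carry the mitosis shift, whose median was −1.16 without it.

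**Figure D3:**
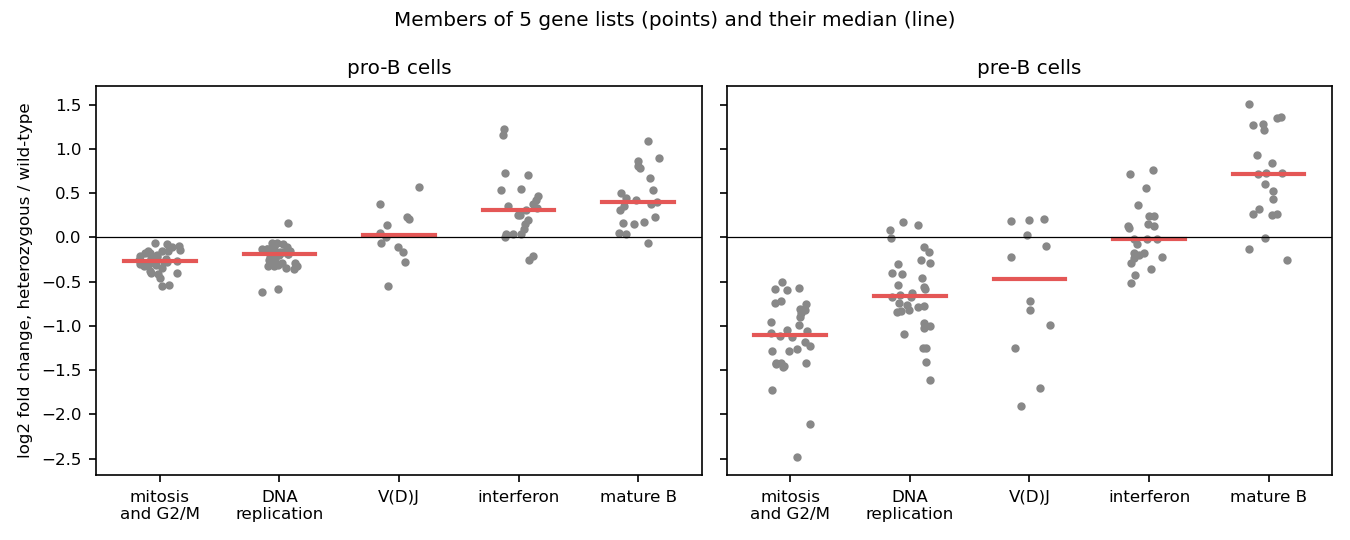
Log2 fold change of heterozygous against wild-type cells (vertical axis) for each measured member of 5 gene lists, in pro-B and in pre-B cells (horizontal axis). Points are genes and lines are list medians: all 32 mitosis genes lie below 0 at both stages, with medians of −0.26 and −1.10.

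Mature B cell markers went the other way in pre-B cells. Their median was 0.71, with 18 of 21 above 0 (camera adjusted p = 8.23e-09; adjusted p = 0.569 with an estimated correlation), and 0.85 and 0.49 within replicates. Without wild-type pre-B replicate 1 it was 0.31. Over all genes 0 passed, and adjusted over the list alone 5 rose, 8 with the block. Cxcr5 rose by 1.36 ± 0.28 (adjusted p = 0.0332 over the list alone), Cd40, a costimulatory receptor, by 0.84 ± 0.20 (0.0354), Ciita, the regulator of class II antigen presentation, by 1.34 ± 0.34 (0.0356) and Cd74 by 1.21 ± 0.34 (0.0422). Ighm, the most abundant member at a mean of 13.1, had −0.25 ± 0.19.

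V(D)J recombination genes, which rearrange the antigen receptor loci, had a median of −0.47 in pre-B cells, with 8 of 12 below 0 (camera adjusted p = 0.0454; adjusted p = 0.607 with an estimated correlation). Within replicates 1 and 2 it was −0.36 and −0.49. Adjusted over the list alone 5 fell. The end-joining genes Polm (−1.70 ± 0.21, adjusted p = 0.000812), Lig4 (−1.91 ± 0.43, adjusted p = 0.016) and Xrcc6 (−0.82, adjusted p = 0.0183) were joined by the recombinase genes Rag2 (−1.25 ± 0.33, adjusted p = 0.0183) and Rag1 (−0.99 ± 0.32, adjusted p = 0.0378). The list call was lost with the block (adjusted p = 0.0724), without either wild-type pro-B array (0.0633), without wild-type pre-B replicate 1 (0.113), without heterozygous pre-B replicate 2 (0.166) and without both pre-B replicate 2 arrays (0.0816). The median was −0.85 without wild-type pre-B replicate 2 and −0.86 without heterozygous pre-B replicate 1.

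The EBF1 and PAX5 list had a median of −0.21 in pre-B cells, with 9 of 26 members above 0 and 17 below (adjusted p = 0.5). Adjusted over the list alone, Bst1 fell (−1.48 ± 0.21, adjusted p = 0.00439) while Cxcr5 (adjusted p = 0.0206) and the inhibitory receptor gene Cd22 (0.68 ± 0.17, adjusted p = 0.0481) rose. Pax5 had 0.42, Cd79a −0.21, Igll1 0.13 and Vpreb1 0.20, none of which passed, and Rag1 did not pass in this list (adjusted p = 0.0761). Small pre-B stage markers did not pass as a list (median −0.23, adjusted p = 0.4), and adjusted over the list alone Il2ra (−1.30 ± 0.30), Rag2 and the transcription factor gene Spib (−0.76) fell and Cd22 rose (adjusted p = 0.0336 each). In the IL-7 receptor list, adjusted over the list alone, Ccnd3 (−1.25, adjusted p = 0.021), Bcl2l1 (−0.76) and Pim2 (−0.80) fell, and the survival gene Bcl2 rose (1.24, adjusted p = 0.0398). Myc had 0.22 and the pro-B marker Spn, which encodes CD43, 0.56, and neither passed.

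Averaged over both stages 4 lists passed, mitosis, mature B cell markers, DNA replication and interferon response. V(D)J recombination (camera adjusted p = 0.149), the dendritic list (0.149) and MYC targets (0.96), each called at 1 stage, did not. The mitosis median was −0.67, with 32 of 32 below 0 (camera adjusted p = 2.47e-20; adjusted p = 0.508 with an estimated correlation). Adjusted over the list alone 21 fell, 27 with the block, among them Ect2 (−1.47 ± 0.20) and Kif11 (−0.91 ± 0.14, adjusted p = 0.00404 both). The mature B median was 0.58, with 20 of 21 above 0 (camera adjusted p = 5.24e-13; adjusted p = 0.39 with an estimated correlation), or 0.32 without wild-type pre-B replicate 1, and 5 rose adjusted over the list alone, 12 with the block. These included Cxcr5 (1.22 ± 0.20, adjusted p = 0.00768) and Cd40 (0.76 ± 0.14, adjusted p = 0.00887). DNA replication had a median of −0.41 (camera adjusted p = 2.37e-11; adjusted p = 0.39 with an estimated correlation), and 5 genes fell adjusted over the list alone, 13 with the block, led by Cdc45 (−0.77), Cdc6 (−0.98) and E2f2 (−0.69, adjusted p = 0.0163). Of 34 splits of the 8 arrays, 2 gave a mitosis and 3 a mature B median as large, the real one included, so chance was not excluded. None of the others among these balanced the stages, and in the 18 splits that do, too few for a share under 0.05, genotype gave the largest of both medians. The interferon list passed with a median of 0.15 and 15 of 23 above 0 (adjusted p = 0.0304; adjusted p = 0.843 with an estimated correlation). It was lost without wild-type pro-B replicate 2 (adjusted p = 0.192), heterozygous pro-B replicate 1 (median 0.059, 0.269), wild-type pre-B replicate 2 (0.076, 0.316) or heterozygous pre-B replicate 1 (0.032, 0.367), and with no filter (0.0564). The median was 0.26 without heterozygous pro-B replicate 2 and 0.066 without the genes that differ between the pre-B replicates. Oasl2 had 0.73 in this list. The EBF1 and PAX5 median was −0.01 (adjusted p = 0.96).

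Whether the genotype difference itself depended on stage was tested as an interaction. No gene passed in limma (0 of 11003, smallest adjusted p = 0.571), with 569 genes at an unadjusted p under 0.05, and the block also gave 0. Below 0, the largest evidence belonged to the proline catabolism gene Prodh (−2.21 ± 0.30, n = 2 arrays a group) and Epb41l4b (−2.43 ± 0.34, adjusted p = 0.571 both), then Pls3 (−2.08 ± 0.35), Dnaaf5 (−1.61 ± 0.28) and Tax1bp3 (−1.88 ± 0.33, adjusted p = 0.654 each). Above 0 it belonged to Nid1 (2.04 ± 0.33), St8sia6 (3.61 ± 0.60), Mmp14 (1.52 ± 0.26, adjusted p = 0.654 each), Snx14 (1.23 ± 0.23) and Pgap1 (2.5 ± 0.48, adjusted p = 0.664 both). So, adjusted over all genes, no genotype effect was shown to differ between the stages.

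Of the lists, mitosis had an interaction median of −0.80 with 32 of 32 below 0 (camera adjusted p = 1.16e-11; adjusted p = 0.663 with an estimated correlation), and 1 gene, Ect2, passed adjusted over the list alone (−2.02 ± 0.41, adjusted p = 0.0484). Without wild-type pre-B replicate 1 the mitosis median was −0.53. DNA replication had −0.45 (adjusted p = 0.00128; adjusted p = 0.663 with an estimated correlation), with Cdc45 at −1.28 and 0 genes passing adjusted over the list alone. Its call was lost without wild-type pre-B replicate 1, where the median was −0.24 (adjusted p = 0.336), and without heterozygous pre-B replicate 2 (−0.29, 0.0681). V(D)J recombination had −0.32 (adjusted p = 0.0172; adjusted p = 0.663 with an estimated correlation), and adjusted over the list alone Polm (−1.59, adjusted p = 0.0112) and Xrcc6 (−1.19, adjusted p = 0.031) passed, 5 members with the block. This was lost without wild-type pro-B replicate 2 (0.0568), wild-type pre-B replicate 1 (median −0.60, 0.142) or heterozygous pre-B replicate 2 (−0.53, 0.112), with medians further from 0. It was kept, at −0.77, −0.59 and −0.56, without wild-type pre-B replicate 2, heterozygous pre-B replicate 1 or both pre-B replicate 2 arrays. MYC targets had 0.18 (adjusted p = 0.0235) and the 8 plasma cell markers −0.39 (adjusted p = 0.0387), with Creb3l2 at −1.42 and Irf4 at −0.79 and 0 members of either list passing adjusted over the list alone. Both had an adjusted p = 0.663 with an estimated correlation.

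The MYC interaction was lost without wild-type pro-B replicate 1 (adjusted p = 0.0513) or 2 (0.0568), heterozygous pro-B replicate 2 (median 0.029, 0.365), wild-type pre-B replicate 1 (median 0.097, 0.308) or heterozygous pre-B replicate 2 (0.0681), and with no filter (0.106). Its median was 0.33 without heterozygous pro-B replicate 1 and 0.33 without both pre-B replicate 2 arrays. That of the plasma cell markers was lost without wild-type pro-B replicate 1 (0.0843) or 2 (0.0568), heterozygous pro-B replicate 1 (0.114), wild-type pre-B replicate 1 (0.105), or heterozygous pre-B replicate 1 (0.0511) or 2 (0.115), without both pre-B replicate 2 arrays (0.0524) and with no filter (0.106). Mature B cell markers did not pass (0.17, adjusted p = 0.0571).

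The stage comparison in wild-type cells asked how pre-B cells differed from pro-B cells, and also checked the sort labels. Arpp21 fell (−5.91 ± 0.36, SE, n = 2 arrays a group) from 8.79 to 2.88, below the filter. The surrogate light chain genes Igll1 (−4.70 ± 0.85) and Vpreb1 (−4.19 ± 0.67), which form the pre-B cell receptor, and Dntt (−4.18 ± 0.67), which adds nucleotides at V(D)J junctions, fell as well. Fcer2a, the low-affinity IgE receptor of mature B cells, rose by 5.36 ± 0.44, from 3.93, below the filter, to 9.29. Other B-cell surface genes that rose included Cd83 (4.26 ± 0.50), Ccr6 (3.92 ± 0.36) and Gpr183 (3.99 ± 0.43).

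In all 1512 genes passed, 535 higher and 977 lower in pre-B cells. The 12 with the largest rise also held Tlr1 (4.56), Marchf1 (4.52), P2ry10 (4.44), Ctsh (4.42), the light-chain gene Iglv1 (4.36), Egr3 (4.19), H2-DMb2 (4.0) and Reln (3.97), at adjusted p from 0.00119 for Iglv1 to 0.00522 for Reln. The 12 with the largest fall also held Emp1 (−5.03), Cracdl (−4.87), Mmrn1 (−4.36), Klhl32 (−4.22), Car3 (−4.20), Mfsd13a (−3.97), Tmem255a (−3.94) and Selenom (−3.90), at adjusted p from 0.00119 for Cracdl to 0.0254 for Mfsd13a. Another probe set of Egr3 gave 0.00 and one of Emp1 0.09, and a dim one of Igll1 gave 0.73. Other probe sets of Mfsd13a gave −0.34 and 0.18, and without _x_at and _s_at probe sets its call was lost (−0.34, adjusted p = 0.33). The 4 wild-type arrays alone ended the calls of Mfsd13a (0.0822) and Igll1 (0.0544), and the mean of its probe sets that of Igll1 (−1.98, adjusted p = 0.0784). With the block 2031 genes passed, all 1512 among them. The count was 345 without wild-type pro-B replicate 2, 619 without wild-type pro-B replicate 1, 938 and 940 without wild-type pre-B replicates 1 and 2, and 943 without either heterozygous pro-B array. Without wild-type pro-B replicate 2, calls were lost for Igll1 (adjusted p = 0.088), Vpreb1 (0.0717), Dntt (0.0745), Mfsd13a (0.156) and Selenom (0.0509). Without replicate 1 those of Igll1 (0.0752) and Mfsd13a (0.0763) were, and that of Mfsd13a without either heterozygous pro-B array (0.0552).

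Dividing-cell genes fell from pro-B to pre-B. In the mitosis list 31 of 32 members fell over all genes and 32 adjusted over the list alone, with a median of −2.27 (camera adjusted p = 3.35e-23; adjusted p = 0.253 with an estimated correlation), Kif11 at −2.55 ± 0.19 and Aurka at −2.58 ± 0.21. In DNA replication 29 of 34 fell, 33 adjusted over the list alone, with a median of −1.84 (camera adjusted p = 3.59e-20; adjusted p = 0.122 with an estimated correlation), Cdc45 at −2.17 and Gins2 at −2.96. Of 30 MYC targets 11 fell, 16 adjusted over the list alone (median −0.69, camera adjusted p = 3.76e-08; adjusted p = 0.276 with an estimated correlation), such as Srm (−2.20 ± 0.24) and Ncl (−1.11). Myc itself fell by 2.02 ± 0.35 (adjusted p = 0.0113). Of 32 oxidative phosphorylation genes 4 fell, 5 adjusted over the list alone (median −0.47, camera adjusted p = 6.4e-07; adjusted p = 0.397 with an estimated correlation). Among 16 glycolysis genes Ldha (−1.48) and Gapdh (−0.95) fell, and the list median of −0.72 only just passed (adjusted p = 0.0493; adjusted p = 0.741 with an estimated correlation). The glycolysis call was lost with the block (adjusted p = 0.0727), without wild-type pro-B replicate 2 (0.103), wild-type pre-B replicate 1 (median −0.26, 0.393) or either heterozygous pre-B array (0.0515).

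B-cell maturation genes stood higher in pre-B than in pro-B cells. Mature B cells in the pre-B gate could raise the mature B markers too, which was not tested here. Of 21 mature B cell markers 19 rose, 20 adjusted over the list alone, with a median of 2.46 (camera adjusted p = 3.59e-20; adjusted p = 0.122 with an estimated correlation), Ms4a1, which encodes CD20, at 3.82 ± 0.37, Fcrl1 at 3.66 ± 0.23 and Cd40 at 3.22 ± 0.20. Of 22 small pre-B markers 11 rose and 0 fell, and adjusted over the list alone 15 rose and 1 fell (median 0.78, camera adjusted p = 5.4e-09; adjusted p = 0.231 with an estimated correlation). Cd2 (2.96 ± 0.30), Cd22 (1.75 ± 0.17) and Il2ra (1.95 ± 0.30, adjusted p = 0.0079) rose, while Rag1 (0.73 ± 0.32, adjusted p = 0.184) did not pass. Of 18 pro-B markers 9 fell and 1 rose, also adjusted over the list alone (median −0.67, camera adjusted p = 0.000435; adjusted p = 0.122 with an estimated correlation), with Spn at −1.61 ± 0.25, the transcription factor gene Erg at −3.42 ± 0.52 and Meis1 at −1.79. In the EBF1 and PAX5 list 11 of 26 rose and 4 fell, and adjusted over the list alone 14 and 4 (median 0.71, camera adjusted p = 0.000642; adjusted p = 0.271 with an estimated correlation). Bank1 (3.33 ± 0.32), Cxcr5 (2.24 ± 0.28) and Cd79a (0.95 ± 0.19, adjusted p = 0.0205) rose, Lef1 fell (−2.45 ± 0.29), and Pax5 (0.43 ± 0.39, adjusted p = 0.534) did not pass. The dendritic list passed only just (median 0.17, adjusted p = 0.044; adjusted p = 0.355 with an estimated correlation), through Ly6d (2.28), Spib (1.16) and Cox6a2 (1.03). It was lost without wild-type pro-B replicate 2 (0.0599), wild-type pre-B replicate 2 (0.135), either heterozygous pre-B array (0.0515) or both pre-B replicate 2 arrays (0.171), and with the block within stage (0.0609). Single genes of lists that did not pass rose too, such as Pim2 (2.39 ± 0.22), Polm (1.86 ± 0.21), Notch2 (2.94 ± 0.18) and Dtx1 (2.27), while Socs2 (−3.17) and Hes1 (−2.23 ± 0.25) fell.

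Granulocyte and erythroid genes stood higher in pre-B cells mainly on replicate 2 arrays, a difference between replicates that was not tested. The granulocyte and monocyte list had a pooled stage median of 1.81 in wild-type cells (camera adjusted p = 0.0167; adjusted p = 0.784 with an estimated correlation), made up of −0.18 within replicate 1 and 3.95 within replicate 2. Without wild-type pre-B replicate 2 it was −0.38 (adjusted p = 0.95). Of 20 members 1 passed, Cybb (2.62 ± 0.39). The erythroid and megakaryocyte list had 0.96 (adjusted p = 0.0493; adjusted p = 0.774 with an estimated correlation), made up of 0.06 and 1.75, with 0 members passing over all genes or adjusted over the list alone. It was lost with no filter (0.0521), after renewed quantile normalization (0.0883) and without wild-type pro-B replicate 1 (median 0.62, 0.101) or 2 (0.0599), and was −0.18 without wild-type pre-B replicate 2 (0.934). In heterozygotes the granulocyte list had 2.54 (adjusted p = 0.00217; adjusted p = 0.783 with an estimated correlation), from −0.07 and 4.61 within replicates, and −0.27 without heterozygous pre-B replicate 2 (0.542). The erythroid list had 0.96 (adjusted p = 0.0184; adjusted p = 0.783 with an estimated correlation), from 0.20 and 2.35, and 0.20 without that array (0.542), and was lost with no filter (0.0562) and after renewed quantile normalization (0.0601). Without the genes that differ between the pre-B replicates, the erythroid medians were 0.35 in wild-type (0.243) and 0.45 in heterozygous cells (0.328). Without the pre-B replicate 1 array of a genotype, the granulocyte medians were 4.56 and 4.97 and the erythroid ones 1.99 and 2.48. The mitosis medians within replicates were −1.99 and −2.56 in wild-type and −2.93 and −3.10 in heterozygous cells. Those of mature B cell markers were 2.33 and 2.97, and 3.08 and 3.22. Neither the granulocyte list (0.08 in pre-B, adjusted p = 0.404) nor the erythroid list (adjusted p = 0.634) passed by genotype.

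**Figure D4:**
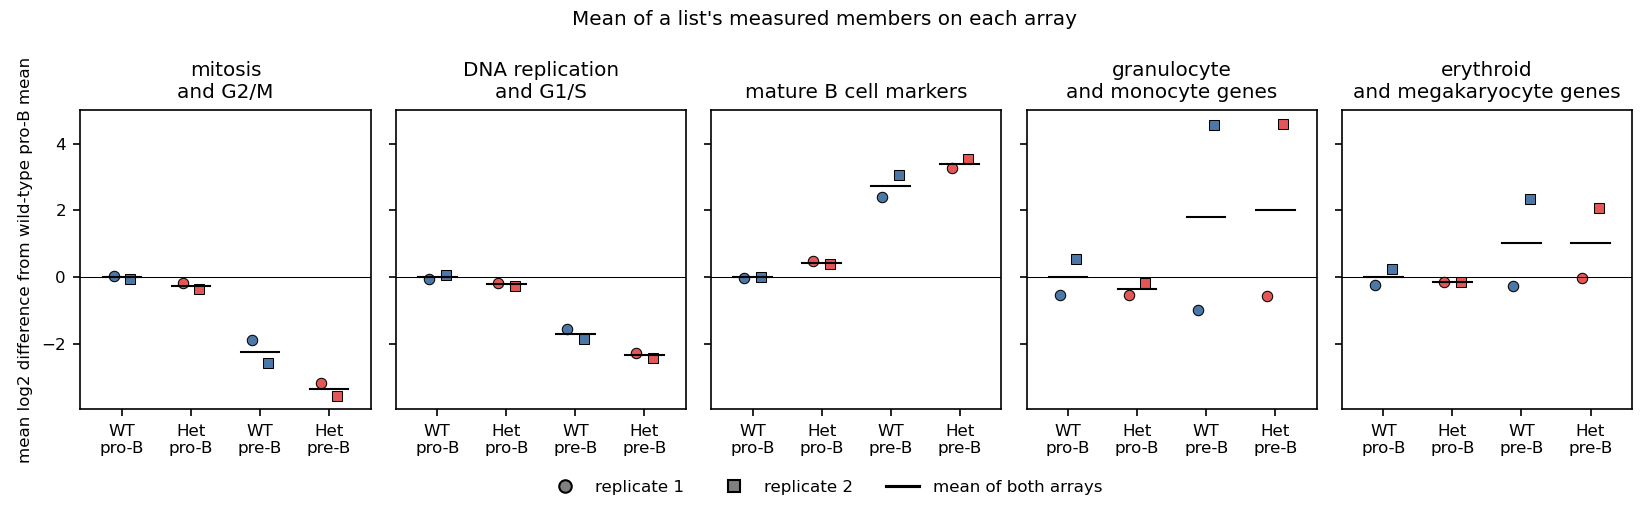
Mean log2 intensity of the members of 5 gene lists on each array, relative to the wild-type pro-B mean (vertical axis), by group (horizontal axis). Circles are replicate 1, squares are replicate 2 and lines are means of both arrays: the granulocyte list parts the pre-B replicates by 5.55 in wild-type and 5.16 in heterozygous cells, while mitosis genes stand lowest on both heterozygous pre-B arrays.

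The same step was then followed in heterozygotes. Fcer2a rose by 6.72 ± 0.44 (SE, n = 2 arrays a group), Ccr6 by 6.13 ± 0.36, Marchf1 by 5.44 ± 0.46, Cd83 by 5.31 ± 0.50 and Gpr183 by 5.12 ± 0.43. Chek1, a checkpoint kinase gene, fell (−5.41 ± 0.52) to a mean of 2.54, below the filter, and Arpp21 (−5.4 ± 0.36), Myl10 (−4.92 ± 0.52), Mmrn1 (−4.88 ± 0.38) and Gfra2 (−4.77 ± 0.56) fell too. Gfra2 rests on an _x_at probe set: its others gave −1.87, −1.11, −0.46 and 0.20, and without _x_at and _s_at probe sets its call was lost (−0.46, adjusted p = 0.133). Adjusted p ran from 0.000552 for Fcer2a to 0.00214 for Gfra2. In all 1997 genes passed, 553 higher and 1444 lower, and 2663 with the block. The count was 731 without heterozygous pro-B replicate 1 and 736 without replicate 2. Stage differences in the 2 genotypes correlated across genes with r = 0.868 and rho = 0.791. They shared 327 genes higher, where 26.9 are expected by chance, and 814 lower, where 128 are expected, and 1 gene passed in opposite directions. The expected counts again take comparisons with a shared spread per gene as independent.

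All 32 mitosis genes fell in heterozygotes, over all genes and adjusted over the list alone (median −3.17, camera adjusted p = 2.78e-23; adjusted p = 0.314 with an estimated correlation), with Ect2 at −4.60 ± 0.29. Of 34 DNA replication genes 31 fell, 33 adjusted over the list alone (median −2.25, camera adjusted p = 1.97e-19; adjusted p = 0.185 with an estimated correlation), such as Cdc45 (−3.45) and Cdc6 (−3.33). Of mature B cell markers 18 of 21 rose, 19 adjusted over the list alone (median 3.22, camera adjusted p = 1.97e-19; adjusted p = 0.185 with an estimated correlation). Among small pre-B markers 9 of 22 rose and 1 fell, and 12 and 1 adjusted over the list alone (median 0.71, camera adjusted p = 3.62e-06; adjusted p = 0.339 with an estimated correlation), Il2ra by 1.15 (adjusted p = 0.0384). Of 18 pro-B markers 9 fell and 1 rose, 10 and 1 adjusted over the list alone (median −1.39, camera adjusted p = 0.00225; adjusted p = 0.185 with an estimated correlation), with Bst1 at −2.34 and Bcl2 at 2.68. Of 32 oxidative phosphorylation genes 11 fell, 19 adjusted over the list alone (median −0.58, camera adjusted p = 3.62e-06; adjusted p = 0.489 with an estimated correlation), and of 30 MYC targets 9 fell either way (median −0.52, camera adjusted p = 0.000495; adjusted p = 0.489 with an estimated correlation).

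V(D)J recombination passed in heterozygotes, where 5 of 12 genes fell, 6 adjusted over the list alone (median −0.81, camera adjusted p = 0.0346; adjusted p = 0.489 with an estimated correlation). These included Rag2 (−2.34 ± 0.33), Dntt (−4.16), Lig4 (−1.84) and Xrcc6 (−1.27), while Rag1 (−0.49) did not pass. The call was lost without heterozygous pre-B replicate 2 (adjusted p = 0.0732) and without the genes that differ between the pre-B replicates (0.0878). Immediate-early genes, induced by stimulation or cell handling, also passed, with 7 of 19 higher and 2 lower by both adjustments (median 0.52, camera adjusted p = 0.0119; adjusted p = 0.408 with an estimated correlation). The median was 0.52 in wild-type cells too, without passing (camera adjusted p = 0.0546), and the interaction did not pass (0.233). In heterozygotes Egr3 (3.38) and Klf6 (2.01) rose and Myc fell (−1.69). The call was lost without heterozygous pre-B replicate 2, one of the pair with granulocyte transcripts (median 0.25). With no filter the median was 0.21, and without both pre-B replicate 2 arrays the adjusted p was 0.0766. The EBF1 and PAX5 list, with 8 of 26 higher and 6 lower, did not pass (median 0.47, adjusted p = 0.0564), and Pax5 had 0.93 without passing.

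Across the 6 comparisons camera with its preset correlation called 42 list shifts, and 0 of the 42 held with an estimated correlation. The rotation test fry, which asks only whether the genes of a list move on balance 1 way, kept 18 of 42, all of them between stages. With fry the adjusted p was 0.0785 for the mitosis, DNA replication and V(D)J lists and 0.171 for mature B cell markers in pre-B cells, 0.988 for every called list in pro-B cells, and 0.167 for the 3 strongest lists averaged over stages. Of 26 lists 10 passed in no comparison: pre-B cell receptor signalling, IL-7 receptor signalling, Notch pathway, p53 targets, ER stress, T cell, NK cell, stem and progenitor, stromal and endothelial, and sex-linked genes. Median and mean differed in sign for several lists that did not pass. In pre-B cells this held for pro-B markers (median 0.12, mean −0.11) and for the Notch pathway (0.08 and −0.12), in pro-B cells for small pre-B markers (−0.07 and 0.00) and IL-7 signalling (0.01 and −0.00), and in the averaged comparison for IL-7 signalling (0.02 and −0.11). No called list differed in sign between its median, its mean and its test.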

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

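The tests on the Ebf1 probe set and the test of small resting pre-B cells were chosen only after the results were seen.

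Ebf1 probe set E stood 5.83-fold higher in heterozygotes averaged over both stages, a signal outside the value per gene that the comparisons used. Of all probe sets 0.00222% (1 of 45037, E itself) rose as much, which argues against a shift shared by the heterozygous arrays. Its rise of 2.54 on the log2 scale may come from a transcript of the targeted allele. This stays open, because neither the position of the probe set nor the altered part of Ebf1 is given in the sources used here. The rise also differed between stages by −1.45 on the log2 scale (adjusted p = 0.0162 over the 5 probe sets, 1 over all).

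The mitosis list stood lower in heterozygous pre-B cells, and its genotype effect differed between stages by a median of −0.80. Without heterozygous pre-B replicate 1 its median was −1.16, which argues against degraded RNA on that array (adjusted p = 0.569 with an estimated correlation over all arrays). With arrays centred it was −1.14, but array medians ran only from 3.97 to 4.09 on the log2 scale, so centring could move it little. Of 10000 random lists matched on expression 0% were as low, which argues against scaling that moves genes of like expression together. A larger share of small resting pre-B cells in the gate may lower the same genes and stays open, since the small pre-B markers had a median of −0.23 with members on both sides of 0 (adjusted p = 0.4). Mature B cells, taken up below for the mature B list (pre-B median 0.71), could lower the mitosis genes too, and this was not tested. Averaged over both stages, 2 of the 34 splits of the arrays gave a median as large in size (real 0.67, highest other 0.77, a split that does not balance the stages; 0.63 among those that do), so chance was not excluded. A biological effect of Ebf1 dose on cell division remains untested beyond these arrays.

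The mature B list stood higher in heterozygotes at both stages. Without heterozygous pre-B replicate 1 its pre-B median was 0.91 (0.31 without wild-type pre-B replicate 1, the lowest), and in pro-B cells, whose arrays do not include it, the list passed (camera adjusted p = 6.78e-09; adjusted p = 0.624 with an estimated correlation), which argues against degraded RNA. With arrays centred the averaged median was 0.55, a step that could move it little. Of 10000 matched random lists 0% were as high, which argues against scaling that moves genes of like expression together. Mature IgM+ B cells, which the sort on IgM should remove, may add to the list and stay open. Ighm, its most abundant member, had −0.25 ± 0.19 in pre-B cells. It cannot decide, being already at 12.9 in wild-type and 13.0 in heterozygous pro-B cells. The next most abundant, H2-Aa (0.32 ± 0.25) and H2-Ab1 (0.71 ± 0.40), lay above 0 in pre-B cells. Of the 34 splits 3 gave an averaged median as large (real 0.58, highest other 0.64, and in size 0.46 among splits that balance the stages), so chance was not excluded here either.

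For the genes called in the averaged comparison, 1 of the 34 splits, the real one, gave as many (real 5 with stage as a covariate, highest other 3, the split by replicate number). Of these splits 16 do not balance the stages, and the 18 that do are too few for a share under 0.05. The count also fell to 0 without any 1 of 6 of the 8 arrays. Other lists whose genotype effect differed between stages by camera were DNA replication (median −0.45), V(D)J recombination (−0.32), MYC targets (0.18) and plasma cell markers (−0.39). These and the mitosis list had an adjusted p = 0.663 with an estimated correlation, and each of these 4 lost its camera call without single arrays, such as wild-type pre-B replicate 1 (adjusted p = 0.336, 0.142, 0.308 and 0.105).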

How the results depend on the processing

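The replicate block within stage, the fit without both pre-B replicate 2 arrays, the fit without the 275 genes that differ between the pre-B replicates, and the shared calls at an unadjusted p under 0.05 were chosen after seeing the data. The cause was not tested where none is given. With 1 array of a group left out, the lone array was assumed to vary like the other groups. Without both pre-B replicate 2 arrays, pre-B cells kept 1 array a genotype and the spread came from the pro-B arrays alone. Those arrays were more alike within a group, so gene counts by genotype in pre-B cells or averaged are not given for that fit. The 275 genes were picked for differing between pre-B replicates, so leaving them out removes genes of wide spread, which may itself raise counts.

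In pro-B cells 1 gene passed; 0 did with the stricter filter, the mean of a gene's probe sets, the eBayes trend, the 4 pro-B arrays alone or without both pre-B replicate 2 arrays, 2 with the replicate block or with every probe set, 3 with the replicate block within stage, 1 without the differing genes, and 0 to 0 without single arrays. In pre-B cells 0 passed in limma, 21 with the stricter filter, 22 with the replicate block and 13 with the eBayes trend. With the block within stage 121 passed, and 31 without the differing genes. In the averaged comparison 8 passed, 5 with the stricter filter, 23 with the block, 1 with every probe set, 0 with the mean of probe sets, 3 with array weights, 43 with the block within stage (all 8 among them), 17 without both pre-B replicate 2 arrays, 10 without the differing genes, and 0 to 6 without single arrays. The interaction gave 0 under every alternative run. The wild-type stage count of 1512 was 903 with its 4 arrays alone and 345 to 1751 without single arrays, and the count of genes changed from pro-B to pre-B in heterozygotes, 1997, was 3054 with every probe set, 2175 without the differing genes, and 731 to 2067 without single arrays.

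The correlation of the pro-B and pre-B differences (0.265) was 0.21 with no filter and 0.153 to 0.273 without single arrays. The share of the first principal component (63.2%) was 53.3% over all probe sets. Ebf1 probe set A, averaged over both stages, was −0.42 after renewed quantile normalization, and −0.63 to −0.31 without single arrays. The ranges were −0.58 to −0.32 for B, −0.72 to −0.48 for C, −0.79 to −0.48 for D and 2.38 to 2.70 for E.

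Directions reversed for 4 list medians. Without heterozygous pro-B replicate 2 the MYC median in pro-B cells was 0.051 (range −0.22 to 0.051). Without both pre-B replicate 2 arrays the wild-type stage medians were −0.38 for granulocyte and −0.18 for erythroid genes, and the granulocyte median was −0.27 in heterozygotes. Without single arrays these ran from −0.38 to 4.56, −0.18 to 1.99 and −0.27 to 4.97. Leaving out the arrays with granulocyte transcripts is what turned these 3. Among the 42 list calls the replicate block ended those of MYC in pro-B cells, V(D)J in pre-B cells and glycolysis between wild-type stages, and no other.

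Of 42 list calls 36 were kept with no filter, 39 with quantile normalization, 39 with the block, 41 with the block within stage, 34 without both pre-B replicate 2 arrays, 37 of 40 without the differing genes, and 31 to 40 without single arrays, against 18 with fry and 0 with an estimated correlation. Medians stayed within −1.44 to −0.81 (mitosis, pre-B), 0.31 to 0.96 (mature B, pre-B), −0.86 to −0.55 (mitosis, averaged) and 0.32 to 0.77 (mature B, averaged) without single arrays. Of 43 calls of named genes, all 43 were kept with the block, the block within stage, centring and the robust prior, 42 with quantile normalization or no filter, 41 with the trend, 38 with array weights or without both pre-B replicate 2 arrays, 35 with every probe set, 29 of 38 with mean probe sets, and 29 to 36 without single arrays. No named gene changed direction under any alternative run: 1513 results of named genes stayed on their side of the threshold, 49 gained a call and 114 lost one. The deposited table holds no detection call or background level, so the filter at a linear intensity of 16.6 stands in for signal over background, and changes in genes below it were left to the alternative with no filter.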

Other observations

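The tests on granulocyte and erythroid genes were chosen only after the result was seen, and the lists described first were picked after their values were seen.

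Notch pathway genes moved both ways in heterozygous pre-B cells. Of 13 measured members, adjusted over the list alone in limma, the receptor gene Notch1 fell by 1.06 ± 0.20 (SE, n = 2 arrays a group, adjusted p = 0.00861), its target Dtx1 by 0.91 ± 0.18 (0.00861) and Il2ra by 1.30 (0.0135). Lfng, which modifies Notch receptors, rose by 0.58 ± 0.17 (0.0363). The list median was 0.08 and did not pass (camera adjusted p = 0.846). Averaged over both stages Dtx1 (−0.71, adjusted p = 0.00961), Il2ra (−0.90, 0.023) and Notch1 (−0.53, 0.0285) fell. In the ER stress list Herpud1 fell in pre-B cells, adjusted over the list alone (−1.05 ± 0.16, adjusted p = 0.005), while the list had a median of −0.26 (camera adjusted p = 0.183). In the plasma cell list, adjusted over the list alone, Creb3l2 (−1.19) and Irf4 (−0.86) fell in pre-B cells (adjusted p = 0.0442 both), with a list median of −0.45 (camera adjusted p = 0.183). None of these genes passed over all genes.

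The passenger segment that a targeted allele carries may hold changed genes near Ebf1 on chromosome 11. Of the 50 measured genes on each side, 10 of 100 had an unadjusted p under 0.05 in the averaged comparison, against 934 of 10860 elsewhere, an odds ratio of 1.18 (Fisher's exact test, p = 0.59), so the test left this open. Strain segments elsewhere could place changed genes side by side. Of 291 genes with p under 0.01, 75 lay within 5 measured genes of another, against a median of 68 in 10000 shuffles (permutation test, p = 0.249), which also leaves it open.

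The higher interferon list in heterozygous pro-B cells could follow the sex of the mice, since replicate number coincided with sex. The list shifted by 0.22 in size on average between replicate numbers, 0.08 in wild-type and −0.36 in heterozygous pro-B cells, and by 0.30 between genotypes. It kept its call with the block (camera adjusted p = 3.36e-05), though not with the block and an estimated correlation (adjusted p = 0.594) or fry (0.947). Both genotypes held 1 array of each sex, which argues against a sex difference alike in both genotypes as its cause. Relative to wild-type pro-B cells the list stood at 0.55 on heterozygous pro-B replicate 1 and 0.13 on replicate 2, so an effect of sex in heterozygotes, or of that array alone, stays open.

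Granulocytes and erythroid cells in the sorted samples may be the source of the transcripts on the pre-B replicate 2 arrays, a hypothesis. Of 37 members of both lists, 81.1% stood over 1 log2 unit higher on replicate 2 than on replicate 1 in both genotypes. Members were kept by a mean over all arrays, which these replicate 2 arrays raise. Elane, for example, stood at 3.02 and 7.13 on wild-type and at 3.06 and 6.56 on heterozygous pre-B replicates 1 and 2. Another 5 granulocyte and 2 erythroid members lay below the filter. The share therefore describes the pattern and is no separate support for such cells. By mean over all arrays the most abundant granulocyte members were S100a8, S100a9 and Ngp. In wild-type pre-B cells they stood at 4.02, 3.85 and 5.53 on replicate 1 and at 12.8, 12.8 and 12.7 on replicate 2, and in heterozygous ones at 6.84, 6.56 and 5.07 against 13.1, 13.2 and 12.7. Of the most abundant erythroid members, Car2 (7.02 and 9.13 in wild-type, 6.88 and 9.06 in heterozygous pre-B cells) and Fech (7.33 and 9.38, 7.18 and 9.35) stood higher on replicate 2. Tfrc, also high in pro-B cells at a wild-type mean of 9.55, did not (9.25 and 9.14, 9.34 and 8.54). Of the 8 measured NK and innate lymphoid genes, 6 in wild-type and 5 in heterozygous pre-B cells also stood over 1 log2 unit higher on replicate 2. The list's medians were 2.32 and 2.64. Another 10 members, Ncr1, Klrk1 and Eomes among them, lay below the filter, so NK cells themselves were not shown. A sort on B220 and CD19 would remove granulocytes and erythroid cells. A difference between female and male mice of like size at both stages would appear in pro-B cells as well. There the granulocyte list differed by 19.1% of the pre-B difference in wild-type and 6.95% in heterozygous cells, which argues against such a difference. Still, 8 of 20 members in wild-type (mean 1.06) and 2 in heterozygous pro-B cells (mean 0.36) stood over 1 log2 unit higher on replicate 2. A sex difference larger in pre-B cells stays open.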
